A study of Rattus norvegicus with 12 samples.

How the data were processed

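Circular RNAs were measured by sequencing in liver of Wistar rats made diabetic by 4 weeks of a high-fat diet, with 60% of calories as fat, and 1 dose of streptozotocin, a toxin of pancreatic beta cells, at 35 mg/kg after 16 h of fasting. Per the labels, rats above 16.7 mmol/L fasting glucose 3 days later were then assigned to sleeve gastrectomy, an operation that removes most of the stomach, or to a sham operation. The series holds 12 libraries: 5 from rats after sleeve gastrectomy, taken 3 months after surgery, 5 from sham-operated rats, and 2 from rats whose diabetes relapsed after sleeve gastrectomy. The sampling time of the sham and relapse groups and the feeding state at sampling are not given in the sources used here. Ribosomal RNA had been depleted and linear RNA digested with RNase R, so that the libraries were enriched in circRNAs. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples.

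The deposited table gives for each circRNA its type, host gene, chromosome, start, end, strand and number of exons, with a count of back-splice junction reads per library and a normalised value called SRPBM. The processing notes of the submitters name cutadapt 1.9, FastQC, TopHat2 2.0.10 and the rat genome build Rnor_6.0, and do not state how the back-splice reads were called. The counts were whole numbers with totals that differed between libraries, so the count columns deposited by the authors were read as raw back-splice read counts. Within each library the authors' SRPBM was the count multiplied by 1 constant, and SRPBM was not used further. Coordinates are those of Rnor_6.0, counted from 1.

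The table held 21876 entries. Of these, 18175 named the host gene by its symbol and 3701 named it by an Ensembl identifier or as intergenic, and these are called symbol entries and identifier entries here. The 2 kinds differed in their counts: 38.1% of the values above 0 in symbol entries were a single read, against 1.68% in identifier entries. The 21876 entries described 21068 junctions, because 808 junctions were written as 2 entries, one of each kind. In 794 of these pairs no library had reads in both entries. Entries were tested as deposited, and a second test summed the entries of a junction. For host genes, identifiers were joined to symbols through symbol entries that shared the gene record, the transcript or the junction (1444 of 1696 identifiers). The counts of all entries of a host gene were then summed, which gave 6026 hosts. The columns of all 12 libraries were used.

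Tests used edgeR 4.0.16 in R 4.3.3: TMM normalisation, 1 fit with a mean for each of the 3 groups, robust quasi-likelihood dispersion and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a false discovery rate (FDR) threshold of 0.05. The filter filterByExpr, with a minimum count of 5 and a minimum total of 15, left 1525 circRNA entries, 1519 summed junctions and 1337 host genes. Counts-per-million (CPM) of named circRNAs and host genes were scaled to the reads of the tested entries or hosts after TMM. The exception is the ranking of the conserved hosts, where CPM were scaled to all host-gene reads without TMM. Levels in reads-per-million (RPM) were scaled to all back-splice reads of a library. The libraries held 18176 to 37229 such reads, so that a count of 0 allows up to 165 RPM in the smallest library. Where a group had 0 reads, its fold is given as a lower bound against 3 reads over the whole group. The other group enters at its pooled level, so its own counting error and spread between libraries are not part of the bound. Intervals and floors cover counting error only.

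Before the data were examined, the comparisons, the tests, 22 gene lists, the alternative settings and the rule for naming genes were fixed. The lists were glucose production and glycogen, insulin signalling, lipid synthesis and storage, fatty acid oxidation and ketogenesis, cholesterol and bile acids, xenobiotic metabolism, secreted proteins and complement of hepatocytes, amino acids and urea cycle, mitochondria and tricarboxylic acid cycle, endoplasmic reticulum stress, circadian clock, stellate cells and matrix, Kupffer cells and macrophages, lymphocytes and granulocytes, liver endothelium, cholangiocytes, erythroid cells and platelets, the neighbouring pancreas and gut, cell cycle and regeneration, inflammation, circRNA processing factors, and widely conserved circRNA hosts. The 12 lists with at least 5 tested hosts were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all from limma 3.58.1. By the naming rule, each comparison names its circRNAs and hosts past the threshold, filled by the smallest p to 10 circRNAs and 4 hosts, and up to 2 hosts of each list; 3 of the hosts that the rule names are not reported here. The 10 most abundant circRNAs and the 5 most abundant conserved hosts are named as well.

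Single values per library (reads, detected circRNAs, shares by type, list sums) were compared with exact 2-sided permutation tests of the difference in means in scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15. The list sums were not among the tests fixed beforehand. A pseudo-F of the distances between libraries (1 minus the Spearman correlation) was tested by exact enumeration of all splits, 252 for 5 against 5 libraries and 21 for 2 against 5. Figures were drawn with matplotlib 3.10.9.

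The alternatives fixed in that way were size factors of DESeq2 1.42.0 in edgeR, library totals without further normalisation, the DESeq2 Wald test, limma-voom with sample quality weights, no filter, a minimum count of 10, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were summing the entries of a junction, host names as written in the table, and symbol entries only. The tests were also tested on simulated data, with the depth and fitted spread of these libraries and 200 changed items. Recovery is counted among the changed items that passed the filter in the simulated counts. Changed items lost to the filter are left out. At a 4-fold change, 48 of 90 hosts (53.3%) were recovered for sleeve gastrectomy against sham, 39 of 90 (43.3%) for relapse against sleeve gastrectomy and 36 of 89 (40.4%) for relapse against sham. The recovered circRNA entries at 4-fold were 22 of 92 (23.9%), 6 of 86 (6.98%) and 18 of 89 (20.2%). At 2-fold, 12 of 93, 8 of 87 and 7 of 85 hosts were recovered. For lists, only xenobiotic metabolism was raised, with all its genes at 2-fold, and it passed in camera at the preset correlation in each of the 3 comparisons. Its counts were drawn independently for each gene. The power for smaller lists or for lists with correlated genes was not simulated. Linear RNA and the reads themselves were not analysed here.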

Results

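CircRNAs, closed RNA loops recognised by reads across a back-splice junction, were counted in 12 liver libraries: 5 from sham-operated diabetic rats, 5 from diabetic rats after sleeve gastrectomy and 2 from rats with relapse of diabetes after that operation. The depth was 18176 to 37229 back-splice reads per library. The sham libraries 1 to 5 held 30213, 18176, 19212, 19943 and 21509 reads. The sleeve gastrectomy libraries 1 to 5 held 21161, 20352, 18541, 30520 and 29205 reads, and the relapse libraries 1 and 2 held 18473 and 37229 reads. Means were 21811 ± 4851 reads (SD, n = 5) in sham, 23956 ± 5495 (SD, n = 5) after sleeve gastrectomy and 27851 ± 13262 (SD, n = 2) in relapse. A count of 0 allowed up to 165 reads-per-million (RPM) in the smallest library and up to 27.5 over the sham group, 25.05 over the sleeve gastrectomy group and 53.9 over the relapse group.

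Each library detected 3260 to 5368 circRNAs, counted as entries of the table, with 4202 ± 660 (SD, n = 5) in sham, 4388 ± 818 (SD, n = 5) after sleeve gastrectomy and 4311 ± 1486 (SD, n = 2) in relapse. The exact permutation p for detected circRNAs was 0.754 for sleeve gastrectomy against sham, 0.952 for relapse against sleeve gastrectomy and 1 for relapse against sham, and for read totals 0.524, 0.619 and 0.476. Of the 21068 distinct junctions, 12684 (60.2%) were read in a single library and 527 in all 12. Exonic circRNAs took 83.9 ± 0.886% of the reads in sham, 83.4 ± 1.68% after sleeve gastrectomy and 83.9 ± 0.979% in relapse (SD, n = 5, 5 and 2). Intronic circRNAs took 5.64 ± 0.604%, 6.42 ± 0.561% and 6.50 ± 1.07%, and intergenic circRNAs took 10.4 ± 0.981%, 10.2 ± 1.81% and 9.62 ± 0.0873%. The smallest p among the 9 comparisons of types was that of intronic circRNAs after sleeve gastrectomy against sham (exact permutation p = 0.0635, adjusted 0.571).

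**Figure D1:**
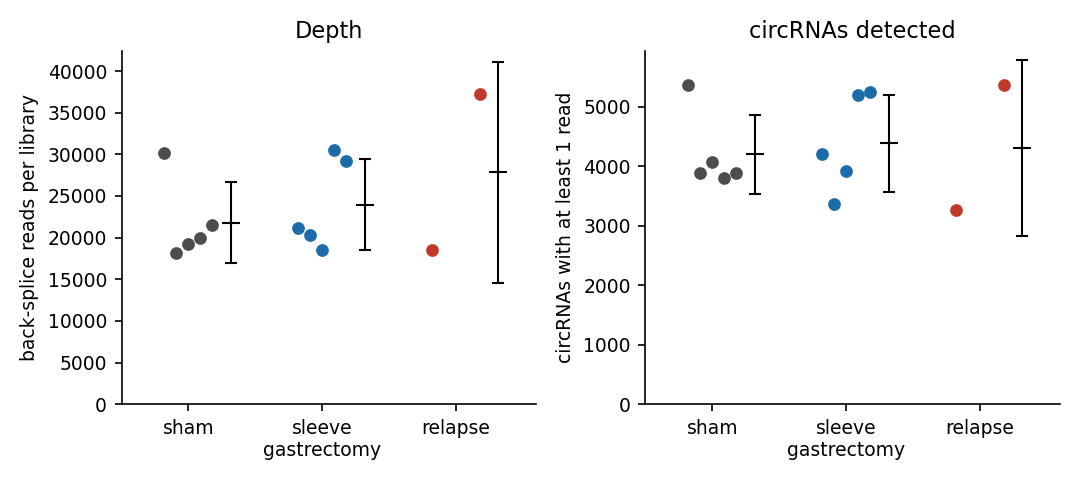
Back-splice reads (left) and circRNAs with at least 1 read (right) in each library, one point per library, with the mean and SD of each group as bars. Sham 1, at 30213 reads and 5368 circRNAs, lies above the other sham libraries, and the 2 relapse libraries lie far apart at 18473 and 37229 reads.

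The most abundant circRNA was circRNA278 of Spidr, a gene of DNA double-strand break repair, at chromosome 11, 89175426 to 89180448, with 20090.0 ± 3164 RPM (SD, n = 12). It was followed by circRNA820 of Nf1x (chromosome 19, 25886357 to 25886887), with 18183 ± 3244, by the intergenic circRNA6045 (chromosome 2, 224802843 to 224803455), with 12184 ± 9576, the largest SD of the 10 most abundant, and by circRNA508 of Cdyl, a chromatin co-repressor (chromosome 17, 29730438 to 29731094), with 10612 ± 2031. Enzymes of drug and steroid metabolism gave several of the 10: circRNA2473 of Ugt2b35, a glucuronosyltransferase, with 8458 ± 5597, circRNA2052 and circRNA2050 of Cyp2c7, a cytochrome P450, with 8399 ± 1873 and 6503 ± 1613, and circRNA2223 of Sult1c3, a sulfotransferase, with 6385 ± 2807. The remaining members were the intergenic circRNA2673 with 7229 ± 1368 and circRNA2745 of Ralgps2, a guanine nucleotide exchange factor, with 5858 ± 1899. None of the 10 passed the threshold in edgeR in any comparison. The junction of circRNA2473 is also written as circRNA9738. Of the widely conserved circRNA hosts, the 5 most abundant were Nf1x with 20323 ± 3605 CPM (SD, n = 12), Cdyl with 12626 ± 2513, Psd3 with 6086 ± 1271, Rere with 4909 ± 736 and Homer1 with 3342 ± 1831. These 5 levels were scaled to all host-gene reads of a library, without the filter or TMM, unlike the CPM given elsewhere. None of these hosts passed in any comparison.

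The comparison of sleeve gastrectomy with sham asks how the operation goes with liver circRNA levels in diabetic rats. CircRNAs of Dennd1b and Upp2 were lower after sleeve gastrectomy. Dennd1b, which activates Rab35 in membrane traffic, had 2310.1 ± 806 CPM in sham (SD, n = 5) and 775 ± 355 after sleeve gastrectomy (SD, n = 5), from 198 and 68 reads. Upp2, a liver uridine phosphorylase that degrades pyrimidine nucleosides, had 4501 ± 1411 CPM in sham and 1927 ± 649.6 after sleeve gastrectomy, from 374 and 180.0 reads. In both genes 5 of 5 sleeve gastrectomy libraries lay below the sham mean. The relapse libraries had 1124 ± 391 CPM (SD, n = 2) of Dennd1b and 2148 ± 826 (SD, n = 2) of Upp2.

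In the edgeR test of summed host counts, Dennd1b had a log2 fold change of −1.60 (SE 0.34, adjusted p = 0.0145) and Upp2 of −1.22 (SE 0.27, adjusted p = 0.0145). They were the 2 hosts of 1337 past the threshold, and both were lower. At an unadjusted p under 0.05 there were 50 hosts, where 66.85 would arise by chance, and DESeq2 called 0 and limma-voom 2. The hosts next in order of p did not pass: Agmo, which cleaves ether lipids, had 2845 ± 774 CPM in sham and 1439 ± 296 after sleeve gastrectomy (adjusted p = 0.328 in edgeR), and Tatdn1 had 332 ± 290.3 CPM in sham and 0 reads after sleeve gastrectomy, at least 9.51-fold lower (adjusted p = 0.328 in edgeR), with 25 of its 26 sham reads in the identifier entry circRNA6143. The host count fell to 0 without sleeve gastrectomy 4 or 5 or without sham 1, 2 or 5, to 1 (Dennd1b) without sleeve gastrectomy 2 or 3 or sham 3, and to 1 (Upp2) without sham 4. It was also 0 with DESeq2, with a minimum count of 10, with the 2 groups alone and with host names as written, and with symbol entries alone Dennd1b had −1.17 and an adjusted p of 0.531 (range over its 10 alternatives other than left-out libraries 0.00505 to 0.745; for Upp2 0.00505 to 0.0814).

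**Figure D2:**
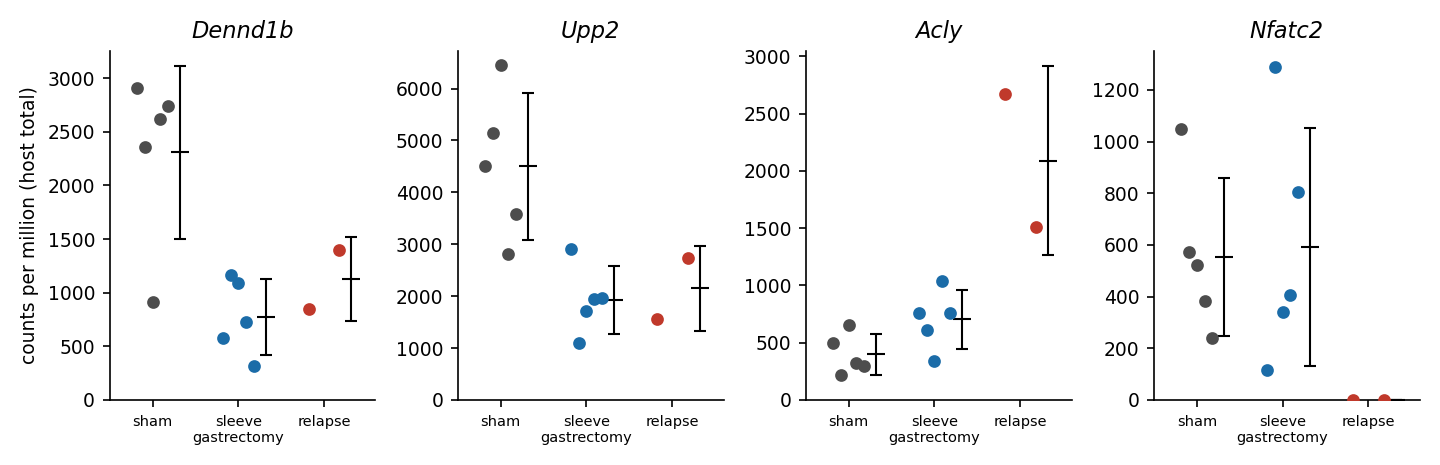
CPM of all circRNAs of Dennd1b, Upp2, Acly and Nfatc2 in each library, one point per library, with the mean and SD of each group as bars. The sleeve gastrectomy libraries lie at 314 to 1164 for Dennd1b against 914 to 2913 in sham, the relapse libraries at 1506 and 2672 for Acly against at most 1042 elsewhere, and at 0 for Nfatc2.

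At the level of single circRNAs, edgeR called 0 of 1525 between sleeve gastrectomy and sham. There were 54 at an unadjusted p under 0.05, where 76.25 would arise by chance, the smallest adjusted p was 0.352, and DESeq2 and limma-voom called 0 as well. Dennd1b and Upp2 were among the hosts of the 10 circRNAs with the smallest p. CircRNA1643 of Upp2 (chromosome 3, 44823074 to 44833052, 4 exons) had 3279 ± 1204 CPM in sham and 1384 ± 490.2 after sleeve gastrectomy (SD, n = 5 and 5). Of Dennd1b on chromosome 13, circRNA62 (56114439 to 56129496) had 1470.05 ± 608 and 654 ± 327 CPM, and circRNA5889 (56114439 to 56121638) had 574 ± 383 and 28.8 ± 64.3 CPM. Pik3c2g, a phosphoinositide kinase, gave circRNA1579 (chromosome 4, 173885674 to 173889303) with 5036 ± 1098 and 3052 ± 1123 CPM, and Dnmbp, an exchange factor for Cdc42, gave circRNA2198 (chromosome 1, 263633066 to 263633397) with 2559 ± 457 and 4134 ± 801 CPM. CircRNA6143 of Tatdn1 (chromosome 7, 98792746 to 98797649), circRNA16525 (chromosome 5, 77248427 to 77341841) and the intronic ciRNA2147 (chromosome 20, 5377360 to 5416741) had 0 reads after sleeve gastrectomy. All 3 are identifier entries, in which counts of 0 were frequent also at abundant junctions. Their sham reads were 5, 11, 6 and 3 in sham 1 to 4 for circRNA6143, 23 and 8 in sham 2 and 5 for circRNA16525, and 13, 10 and 3 in sham 1, 2 and 4 for ciRNA2147.

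The remaining circRNAs of the 10 with the smallest p were one junction written as 2 entries. The junction of Ttc39c at chromosome 18, 4031676 to 4037220, was counted as circRNA2829 in sham 1 to 4 and in both relapse libraries, and as circRNA6961 in sham 5 and all 5 sleeve gastrectomy libraries. Tested apart, circRNA2829 was at least 9.89-fold lower after sleeve gastrectomy than in sham (0 against 27 reads), or at least 6.58-fold without sham 1, and circRNA6961 had 50 reads against 5. Summed, the junction had a log2 fold change of 0.57 (SE 0.52), of opposite sign to that of circRNA2829, and did not pass (edgeR adjusted p = 0.996).

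**Figure D3:**
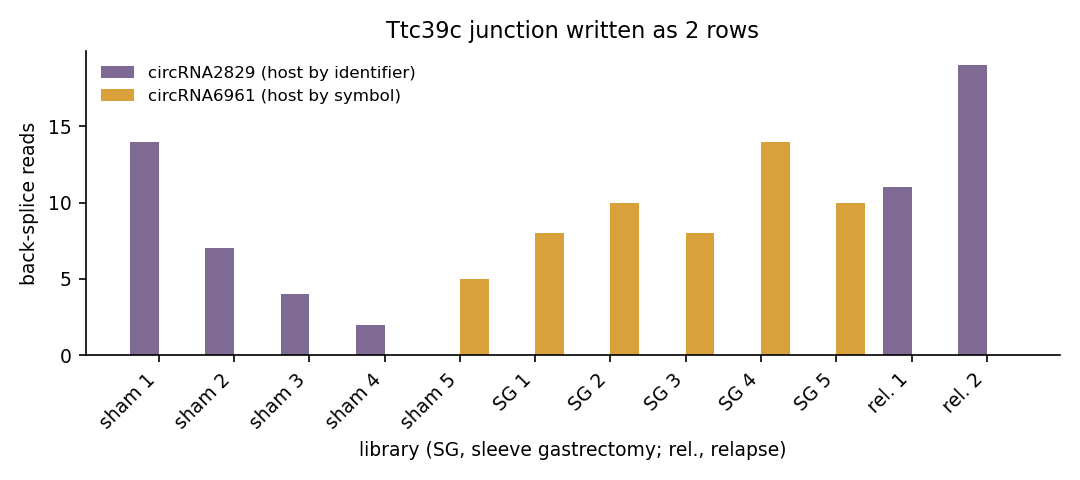
Back-splice reads of the Ttc39c junction on chromosome 18 in each library, with one bar for each of the 2 entries that the table gives it. No library has reads in both entries, and the sleeve gastrectomy libraries hold 8 to 14 reads of circRNA6961 and 0 of circRNA2829.

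Genes of glucose, fatty acid and bile acid metabolism did not pass between sleeve gastrectomy and sham (mean CPM ± SD, n = 5 and 5, sleeve gastrectomy first). Of 9 genes of glucose production and glycogen tested, 0 passed, among them Pck1, the rate-limiting enzyme of gluconeogenesis, with 929 ± 196 against 1408 ± 196 and Tkfc, a triokinase of fructose metabolism, with 567 ± 264 against 284 ± 91.0. Of 16 genes of fatty acid oxidation and ketogenesis, 0 passed. Ppara, the nuclear receptor that induces fatty acid oxidation, had 1010.5 ± 360.0 against 1987 ± 510.2, and Ehhadh, a peroxisomal enzyme of that pathway, had 263 ± 191 against 575 ± 285. Of 12 genes of cholesterol and bile acids, 0 passed, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 47.5 ± 77.8 against 216 ± 229 and Abcb4, the phospholipid exporter of bile, at 362 ± 183 against 111 ± 101. Lipid synthesis and storage had 0 of 9 past, with Acly, the source of cytosolic acetyl-CoA, at 703 ± 255 against 397 ± 177 and Fasn, fatty acid synthase, at 124 ± 167 against 18.2 ± 40.7. None of the 8 genes of insulin signalling passed, with Pik3c2a at 1058 ± 939 against 695 ± 483.

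Of the 18 tested genes of secreted proteins and complement 0 passed after sleeve gastrectomy: haptoglobin (Hp) had 315 ± 255 CPM against 1059 ± 914 in sham and complement C3 had 3683 ± 812 against 2249.9 ± 886 (mean ± SD, n = 5 and 5). Of 7 genes of inflammation, 0 passed over all genes and 1 passed adjusted over the list alone, Irak3, an inhibitor of Toll-like receptor signalling, with 1115 ± 405 against 435 ± 109. Il1r1, the interleukin 1 receptor, had 406 ± 112 against 841 ± 355. Xenobiotic metabolism had 0 of 13 past, with Fmo5 at 264 ± 153 against 106 ± 119. Amino acids and urea cycle had 0 of 22 past, with Cps1, the entry enzyme of the urea cycle, at 5538 ± 2261 against 7498 ± 1877 and Kynu at 481 ± 277 against 831 ± 387. Mitochondria and tricarboxylic acid cycle had 0 of 5 past, with Suclg1 at 85.3 ± 105 against 287 ± 251 and Sucla2 at 308 ± 134 against 155 ± 152. Endoplasmic reticulum stress had 0 of 12 past, with the chaperone Canx at 2133 ± 472 against 2770.4 ± 488 and Pdia3 at 296 ± 231 against 119.9 ± 61.9. The widely conserved circRNA hosts had 0 of 23 past, with Fam120a at 2384 ± 407 against 3529 ± 813 and Homer1 at 3327 ± 1134 against 4966 ± 2670.5.

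In camera 0 of the 12 lists passed between sleeve gastrectomy and sham (smallest adjusted p = 0.868, 0 lists at an unadjusted p under 0.05). With an estimated correlation and with fry the count was 0 as well (smallest adjusted p in fry 0.8288). In the inflammation list Irak3 was the member that passed when adjusted over the list alone, and in the other lists that count was 0. The median, mean and test direction differed in sign for glucose production and for amino acids. The pseudo-F of the profiles was 1.17 and did not pass (exact permutation p = 0.0873 over all splits of 5 against 5 libraries, of which the smallest possible p is 0.00794). Without sleeve gastrectomy 5 the pseudo-F was 1.19 with an exact permutation p of 0.0476.

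The comparison of relapse with sleeve gastrectomy asks what distinguishes livers in which diabetes came back after the operation. CircRNAs of Nfatc2, a transcription factor activated by calcineurin, had 0 reads in both relapse libraries and 592 ± 462 CPM after sleeve gastrectomy (SD, n = 5, 55 reads), at least 8.60-fold lower in relapse, or at least 2.86-fold without relapse 2. Its tested circRNAs lie on chromosome 3, circRNA7962 at 165333441 to 165338806 and circRNA8947 at 165333442 to 165339326. Cyp2c7 had 14879 ± 1593 CPM in relapse (SD, n = 2) and 26373.5 ± 5220.4 after sleeve gastrectomy (SD, n = 5), a log2 fold change of −0.82 (SE 0.24) that did not pass (edgeR adjusted p = 0.349). Pbld1 had 0 reads in relapse and 453 ± 252.04 CPM after sleeve gastrectomy, at least 6.88-fold lower, or at least 2.28-fold without relapse 2, and did not pass (edgeR adjusted p = 0.179). Agmo had 3089 ± 1972 CPM against 1439 ± 296 and did not pass (edgeR adjusted p = 0.544).

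Nfatc2 was the 1 host of 1337 past the threshold in edgeR between relapse and sleeve gastrectomy (adjusted p = 0.0434, below the mean in 2 of 2 relapse libraries). At an unadjusted p under 0.05 there were 58 hosts, where 66.85 would arise by chance, and DESeq2 called 0 and limma-voom 1, which was Cyp2c7. The adjusted p of Nfatc2 ranged from 0.0226 to 0.961 over its 10 alternatives other than left-out libraries and was past the threshold in 4 of them. With symbol entries alone it was 0.842 (edgeR unadjusted p = 0.0123), with 0 reads in relapse against 29, at least 4.54-fold lower, or at least 1.51-fold without relapse 2. Without relapse 1 or sleeve gastrectomy 2, 4 or 5 the count of hosts was 0, and without relapse 2 the 1 host called was ENSRNOG00000049727, from 64 reads of the identifier entry ciRNA177 in relapse 1 alone.

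Single circRNAs between relapse and sleeve gastrectomy gave 0 of 1525 past the threshold in edgeR, with 70 at an unadjusted p under 0.05, where 76.25 would arise by chance, and a smallest adjusted p of 0.153. DESeq2 called 2, circRNA2052 of Cyp2c7 and circRNA9738 of Ugt2b35, and limma-voom called 2, circRNA2829 of Ttc39c and circRNA2133 of Lrp5. CircRNA9738 and circRNA2133 are named after their values were seen. CircRNA9738 shares its junction with circRNA2473, which had 10205 ± 345 RPM in relapse and 6593 ± 6408 after sleeve gastrectomy (SD, n = 2 and 5). A call of circRNA9738 by itself therefore does not show a change of the junction. CircRNA2829 of Ttc39c had the smallest p and was at least 21.5-fold higher in relapse, and circRNA6961 of the same junction was at least 7.75-fold lower, or 2.57-fold without relapse 2; summed, the junction had a log2 fold change of 0.38 (SE 0.64). CircRNA2052 of Cyp2c7 (chromosome 1, 148097769 to 148107916) had 7413 ± 373 CPM in relapse and 13060.0 ± 2592 after sleeve gastrectomy (SD, n = 2 and 5). Hadhb, a subunit of the mitochondrial trifunctional protein of fatty acid oxidation, gave circRNA2493 (chromosome 6, 27573047 to 27582987) with 219 ± 309.5 and 1206 ± 678 CPM. Rab11a, of recycling endosomes, gave circRNA2375 (chromosome 8, 70203323 to 70206310) with 194 ± 68.2 and 958 ± 417 CPM, and Dtnbp1 gave circRNA3508 (chromosome 17, 20098293 to 20109613) with 80.8 ± 114 and 775 ± 435 CPM. At 0 reads in relapse were circRNA8113 of AABR07037451 (chromosome X, 20517912 to 20536573), circRNA6984 of Zfp532 (chromosome 18, 61323690 to 61340634), circRNA7290 of Crot, a peroxisomal carnitine transferase (chromosome 4, 22102428 to 22104879), and the intergenic circRNA8062 (chromosome 4, 58367537 to 58373168), at least 5.12-fold, 4.65-fold, 4.50-fold and 4.81-fold lower, and without relapse 2 at least 1.70-fold, 1.54-fold, 1.49-fold and 1.59-fold. Of these, circRNA8113 and circRNA8062 are identifier entries. Summed with the other entry of its junction, circRNA8113 had a log2 fold change of −1.85 (SE 0.76) and circRNA6984 of −2.25 (SE 1.20), and neither sum passed. Without relapse 1 the count of circRNAs was 1, circRNA2493, an identifier entry with 0 reads in relapse 2. Without relapse 2 it was 6, named after their values were seen: the identifier entries ciRNA177, ciRNA608 and circRNA5976 and the symbol entries circRNA4360 of Coq3, circRNA4742 of Camsap1 and circRNA5158 of Slc18b1. Of these, ciRNA177 was read in relapse 1 alone, and the other 5 had 0 reads in relapse 1 and 15 to 76 in relapse 2.

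Genes of lipid synthesis and of drug metabolism had 1 member each past the threshold between relapse and sleeve gastrectomy when adjusted over the list alone, and 0 over all genes (mean CPM ± SD, n = 2 and 5, relapse first). Of the 9 lipid genes it was Acly, with 2089 ± 825 against 703 ± 255, while Fads2, a fatty acid desaturase, had 1012 ± 44.0 against 1882 ± 713. Of the 13 genes of xenobiotic metabolism it was Cyp2c7, while Cyp2c6v1 had 1469.99 ± 51.0 against 2452 ± 358. Brca1, of DNA repair, was the 1 tested gene of cell cycle and regeneration, so adjusting over that list changes nothing. Its unadjusted p in edgeR was under 0.05, with 35.0 ± 49.5 against 409.7 ± 222. None of the 18 secreted proteins and complement genes passed, with ceruloplasmin (Cp) at 105 ± 149 against 534 ± 333. None of the 9 genes of glucose production and glycogen passed, with Gbe1, the glycogen branching enzyme, at 1431 ± 834 against 891 ± 223 and Phkb, a subunit of phosphorylase kinase, at 3488 ± 1061 against 2509 ± 242. None of the 8 genes of insulin signalling passed, with the insulin receptor (Insr) at 548 ± 314 against 1083 ± 361 and Rps6kb1 at 0 reads against 176 ± 256.

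None of the 16 genes of fatty acid oxidation passed in relapse against sleeve gastrectomy, with Ehhadh at 616 ± 327 CPM against 263 ± 191 and Acaa2 at 52.5 ± 74.3 against 265 ± 170.4 (mean ± SD, n = 2 and 5). Cholesterol and bile acids had 0 of 12 past, with Akr1d1 at 105 ± 149 against 393 ± 218 and Hmgcs1 at 32.6 ± 46.1 against 159.5 ± 174. Amino acids and urea cycle had 0 of 22 past, with Prodh2 at 877 ± 50.9 against 449 ± 177 and Otc at 85.1 ± 28.2 against 341 ± 200.4. Mitochondria had 0 of 5 past, with Suclg2 at 817 ± 412 against 1224 ± 329 and Suclg1 at 231 ± 227 against 85.3 ± 105. Endoplasmic reticulum stress had 0 of 12 past, with Ero1b at 17.5 ± 24.8 against 150.01 ± 109 and Hsp90b1 at 0 reads against 154 ± 298. Inflammation had 0 of 7 past, with Il1r1 at 205 ± 106 against 406 ± 112 and Traf2 at 303 ± 32.3 against 116 ± 96.2. The conserved hosts had 0 of 23 past, with Camsap1 at 430.5 ± 332 against 1061 ± 554 and Crim1 at 1936 ± 212 against 3027 ± 472.

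Camera called 0 of 12 lists between relapse and sleeve gastrectomy (smallest adjusted p = 0.235), and the count was 0 with an estimated correlation and with fry (smallest adjusted p in fry 0.446). The 1 list at an unadjusted p under 0.05 was that of secreted proteins and complement (camera p = 0.0196, with an estimated correlation p = 0.144), of which 3 of 18 genes had a positive fold change. The median, mean and test direction differed in sign for fatty acid oxidation, xenobiotic metabolism, amino acids and inflammation. The pseudo-F of the profiles was 1.07 (exact permutation p = 0.286 over 21 splits, of which the smallest possible p is 0.0476).

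Relapse against sham sets diabetes that came back after surgery beside diabetes without the operation. CircRNAs of Acly, ATP-citrate lyase, were higher in relapse, with 2089 ± 825 CPM (SD, n = 2, 84 reads) against 397 ± 177 in sham (SD, n = 5, 34 reads), and both relapse libraries, at 1506 and 2672 CPM, lay above all the other 10. Most of them were circRNA430 (chromosome 10, 88397109 to 88397582, 2 exons), with 1696 ± 799 CPM against 393 ± 199. CircRNAs of Nfatc2 had 0 reads in relapse and 553 ± 305 CPM in sham (49 reads), at least 8.41-fold lower, or at least 2.79-fold without relapse 2. Ugt2b15, a glucuronosyltransferase of steroids and drugs, had 4664 ± 1792 CPM against 1902 ± 439 and did not pass (edgeR adjusted p = 0.0651), nor did Pbld1, with 0 reads against 446 ± 318 CPM, at least 6.86-fold lower, or at least 2.28-fold without relapse 2 (edgeR adjusted p = 0.0947).

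Acly had a log2 fold change of 2.35 (SE 0.49, edgeR adjusted p = 0.0135) and was higher in 2 of 2 relapse libraries, and Nfatc2 had an edgeR adjusted p of 0.0282 and was lower in 2 of 2. They were the 2 of 1337 hosts past the threshold, with 79 at an unadjusted p under 0.05, where 66.85 would arise by chance, and DESeq2 called 2 (Acly and Ugt2b15) and limma-voom 3 (Acly, Cyp2c7 and LOC297568). Acly passed in 10 of 10 alternatives other than left-out libraries and lost the call without relapse 1 (log2 fold change 1.97, adjusted p = 0.636), and Nfatc2 passed in 4 of 10 (adjusted p 0.0191 to 0.849) and lost the call without relapse 1, relapse 2 or sham 1 (adjusted p = 0.381, 0.191 and 0.221). With symbol entries alone, Nfatc2 had an adjusted p of 0.694 (edgeR unadjusted p = 0.0333), with 0 reads in relapse against 15, at least 2.57-fold lower, or 1.44-fold without sham 2 and 0.855-fold, which bounds nothing, without relapse 2. The host count was 0 without relapse 1, 4 without relapse 2 (Acly, ENSRNOG00000049727, Stag1 and Ugt2b15), 1 without sham 1 and 5 without sham 5 (Acly, LOC297568, Nfatc2, Pbld1 and Slc16a10).

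Among single circRNAs 0 of 1525 passed in edgeR between relapse and sham, with 80 at an unadjusted p under 0.05, where 76.25 would arise by chance, and a smallest adjusted p of 0.636. DESeq2 called 1 (circRNA9738 of Ugt2b35) and limma-voom 0. The other entry of that junction, circRNA2473, had 10205 ± 345 RPM in relapse and 9625 ± 6123 in sham (SD, n = 2 and 5). After circRNA430 of Acly, the named members included the intergenic circRNA2613 (chromosome 13, 113735261 to 113748416), with 9869 ± 2757 CPM in relapse and 5276 ± 688 in sham (SD, n = 2 and 5), and circRNA1854 of Slc33a1, the acetyl-CoA transporter of the endoplasmic reticulum (chromosome 2, 154520980 to 154532393), with 631 ± 35.7 against 29.1 ± 65.1. CircRNA2493 of Hadhb had 219 ± 309.5 against 1380.1 ± 352 CPM and circRNA2052 of Cyp2c7 had 7413 ± 373 against 12730.1 ± 1387. Ppp2r5a, a regulatory subunit of protein phosphatase 2A, gave circRNA122 (chromosome 13, 110049192 to 110052621) with 218 ± 206 against 975 ± 172 CPM, and Map3k5, a stress-activated kinase, gave circRNA1957 (chromosome 1, 15488393 to 15494771) with 891 ± 288 against 2393 ± 1137 CPM. CircRNA8113, circRNA6984 of Zfp532 and circRNA7290 of Crot had 0 reads in relapse and were at least 5.11-fold, 4.94-fold and 4.43-fold lower, or 1.69-fold, 1.64-fold and 1.47-fold without relapse 2. Summed with the other entry of their junctions, circRNA8113, circRNA6984 and circRNA1854 had log2 fold changes of −1.96 (SE 0.77), −2.25 (SE 1.20) and 3.11 (SE 1.18), and none of the 3 sums passed. Without relapse 1 the count of circRNAs was again 1, circRNA2493, and without relapse 2 it was 5, those called against sleeve gastrectomy other than circRNA4360.

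In the list of lipid synthesis and storage, 1 of 9 genes rose in relapse against sham over all genes, Acly, and 2 passed adjusted over the list alone, Acly and Fasn, with Fasn at 679 ± 515 CPM against 18.2 ± 40.7 (mean ± SD, n = 2 and 5, edgeR adjusted p = 0.374 over all genes). Of 13 genes of xenobiotic metabolism 0 passed over all genes and 1 adjusted over the list alone, Cyp2c7, with 14879 ± 1593 against 25856 ± 3633, while Cyp2c6v1 had 1469.99 ± 51.0 against 2894 ± 918. Brca1, the 1 tested gene of its list, had an unadjusted p under 0.05 in edgeR and did not pass over all genes, with 35.0 ± 49.5 against 578 ± 377. None of 16 genes of fatty acid oxidation passed, with Ppara at 912 ± 1.35 against 1987 ± 510.2 and Hadhb at 1162 ± 108 against 2315 ± 630.4. Cholesterol and bile acids had 0 of 12 past, with Cyp7a1 at 0 reads against 216 ± 229, at least 3.26-fold lower, or 1.08-fold without relapse 2, and Hmgcs1 at 32.6 ± 46.1 against 305 ± 306. Glucose production and glycogen had 0 of 9 past, with Gbe1 at 1431 ± 834 against 604 ± 294 and Tkfc at 644 ± 80.5 against 284 ± 91.0.

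None of the 18 secreted proteins and complement genes passed in relapse against sham, with Cp at 105 ± 149 CPM against 595 ± 346 and Mug2 at 1982 ± 1069 against 875 ± 467 (mean ± SD, n = 2 and 5). Insulin signalling had 0 of 8 past, with Insr at 548 ± 314 against 1173 ± 504 and Rps6kb1 at 0 reads against 113 ± 171. Amino acids and urea cycle had 0 of 22 past, with Cps1 at 4281 ± 2367 against 7498 ± 1877 and Aldh4a1 at 1350.3 ± 671 against 711 ± 207. Inflammation had 0 of 7 past, with Il1r1 at 205 ± 106 against 841 ± 355 and Irak3 at 949 ± 788 against 435 ± 109. Mitochondria had 0 of 5 past, with Suclg2 at 817 ± 412 against 1098 ± 298 and Sucla2 at 193 ± 272 against 155 ± 152. Endoplasmic reticulum stress had 0 of 12 past, with Atf6 at 288 ± 38.5 against 606 ± 169 and Ero1b at 17.5 ± 24.8 against 179 ± 130.4. The conserved hosts had 0 of 23 past, with Homer1 at 2277 ± 744 against 4966 ± 2670.5 and Camsap1 at 430.5 ± 332 against 1202 ± 567.

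In camera 0 of 12 lists passed between relapse and sham (smallest adjusted p = 0.457), and 0 passed with an estimated correlation or with fry (smallest adjusted p in fry 0.160). Lipid synthesis and storage was the 1 list at an unadjusted p under 0.05 (camera p = 0.0436, with an estimated correlation p = 0.144), with 5 of 9 fold changes positive. The median and the mean of the mitochondrial list differed in sign. The pseudo-F of the profiles was 1.30 (exact permutation p = 0.0952 over 21 splits), and without relapse 1, with 1 relapse library left, it was 0.815.

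Markers of other liver cell types gave few circRNA reads, and their sums are given as values (RPM, mean ± SD, n = 5 in sham, 5 after sleeve gastrectomy and 2 in relapse). Endothelial genes, of which 4 were tested and 0 passed, summed to 1671 ± 449.95, 1606 ± 614 and 2010 ± 373. Stellate cell and matrix genes, with 0 of 2 past, summed to 736 ± 289, 736 ± 359 and 971 ± 158, and genes of Kupffer cells and macrophages, with 0 of 2 past, to 671 ± 402, 675 ± 367 and 458 ± 188. Erythroid and platelet genes, with 0 of 2 past, summed to 998 ± 323, 808 ± 118 and 1025 ± 81.8, and cholangiocyte genes, with 0 of 1 past, to 242 ± 144, 341 ± 272 and 176 ± 211. Lymphocyte and granulocyte genes, with 0 tested, summed to 217 ± 121, 148 ± 75.4 and 108 ± 153. Of the clock genes 15 had reads and 0 could be tested (305 ± 112, 281 ± 176 and 229 ± 170.4), and of the 28 genes of pancreas and gut 0 had reads. Genes of cell cycle and regeneration summed to 691 ± 438, 631 ± 257 and 296 ± 342, and circRNA processing factors, of which Hnrnpm and Rbfox2 were tested and did not pass, to 1148 ± 147, 1366 ± 482 and 1536 ± 411. In exact permutation tests of the 63 sums, metabolic lists included, the smallest p was 0.0952. The smallest p such a test can give, 0.00794 for 5 against 5 libraries and 0.0476 for 2 against 5, leaves no single sum able to pass when adjusted over 63, so these tests do not show that the sums were equal.

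Whether changes after sleeve gastrectomy turned back in relapse was asked across the 1525 tested circRNAs. The log2 fold changes of sleeve gastrectomy against sham and of relapse against sleeve gastrectomy had a correlation of −0.294 across circRNAs, which are not independent replicates. Both share the sleeve gastrectomy libraries with opposite sign, so a negative value arises without any effect: 50 simulations without effects gave a mean of −0.352 (range −0.426 to −0.284), and their covariance was −0.558 on average, against −0.520 observed. With the sleeve gastrectomy libraries split so that the 2 contrasts shared none, the mean over 20 splits was 0.0347 (range −0.00753 to 0.0677). The observed correlation was therefore no more negative than sharing the libraries gives, and no reversal was detectable at this depth. Without relapse 2 it was −0.168, and without sleeve gastrectomy 3 it was −0.382.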

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

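The tests of 0 counts, of symbol and identifier entries and of the lower relapse library of Acly were chosen after the results had been seen, while library totals alone, left-out libraries, the gene list tests and the splits of the libraries were planned, with the outcomes expected of them written afterwards.

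The first pattern is the presence of 0 counts in abundant junctions. Of 157 entries with a mean of at least 20 reads, 31 had a 0 in some library, 68 zeros in all, and 18 of these zeros ended when the entries of a junction were summed, as in Ttc39c. The 50 that remained argue against counting error, which predicts 1.18e-05 zeros (6.33 with the fitted spread between libraries). Ends placed a few bases away are argued against, since 2 of the 50 stood beside at least 5 reads of a junction with both ends within 20 bases. Absence from a whole group is argued against too, since 0 junctions were at 0 in every library of one group and read in all others. Only 5 junctions were at 0 in 2 to 5 libraries, too few to test smaller effects of the groups. Of identifier junctions 24 of 44 (54.5%) had a 0, against 2 of 113 (1.77%) of symbol junctions (Fisher's exact p = 3.29e-14). This goes with a step of the processing behind identifier entries, such as a separate calling pass. A minimum number of reads by itself would not account for junctions such as circRNA2847, at 0 in sleeve gastrectomy 3 and at 50 to 131 reads elsewhere. Nor would it account for ciRNA248, at 0 in sham 3 and at 25 to 149 reads elsewhere. Which step it was stays open, and the zeros per library numbered 2 to 7.

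A second pattern is that the calls of Dennd1b and Nfatc2 rest partly on identifier entries. These gave 39.4% of the Dennd1b reads in sham and 17.6% after sleeve gastrectomy, and 69.4% and 47.3% of the Nfatc2 reads in sham and after sleeve gastrectomy. With symbol entries alone, Dennd1b had a log2 fold change of −1.17 (SE 0.38, unadjusted p = 0.00296, adjusted p = 0.531) in place of −1.60 (SE 0.34), with its adjusted p at 0.00505 to 0.745 over the alternatives other than left-out libraries, so the call ended with a smaller fold and a larger SE. Nfatc2 had 0 reads in relapse in entries of both kinds. With symbol entries alone its adjusted p against sham was 0.694 (range 0.0191 to 0.849, unadjusted p = 0.0333) and its fitted log2 fold change, which depends on the prior count at 0 reads, −4.72 (SE 2.17) in place of −6.38 (SE 1.46). Against sleeve gastrectomy it was −5.57 (SE 2.16, unadjusted p = 0.0123, adjusted p = 0.842, range 0.0226 to 0.961) in place of −6.46 (SE 1.46), so these calls too ended with a smaller fold and a larger SE. In both hosts the symbol entries alone kept the direction by more than their SE. Symbol reads are part of the sums by which the hosts were called, so they cannot show that identifier entries are not needed for the direction. The loss of the calls is no evidence that identifier entries produced it either. How much of each fold the processing of identifier entries accounts for, and how much the groups, cannot be told apart. Neither host passed on its symbol reads alone (120.0 in sham and 56 after sleeve gastrectomy for Dennd1b, 15 and 29 for Nfatc2). For Nfatc2 they bound the fold in relapse at 2.57 against sham and 4.54 against sleeve gastrectomy, but without relapse 2 at 0.855, which bounds nothing, and 1.51.

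The third pattern is Acly, higher in relapse than in sham. Normalisation is argued against, since with library totals alone its adjusted p was 0.00739 (range over the alternatives other than left-out libraries 0.00725 to 0.0352). A single relapse library is argued against as well, since the lower of the 2 had 1506 CPM against at most 1042 in the other 10 libraries, although without relapse 1 the call ended (log2 fold change 1.97, adjusted p = 0.636). The processing of identifier entries is argued against by the 0 Acly reads from such entries in relapse. What stays open is chance variation between samples, with 2 relapse libraries and no splits run for this comparison. A difference between the groups in relapse, feeding state or time of sampling stays open as well, and none of these was tested. The list of lipid synthesis and storage, to which Acly belongs, did not pass in relapse against sham (camera adjusted p = 0.457, p = 0.144 with an estimated correlation, 5 of 9 fold changes positive).

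The counts of sleeve gastrectomy against sham were set beside 100 of the 126 splits of the 10 libraries into 5 and 5. For host genes, 2 of the 100 splits, the real one included, gave at least the real count of 2. The highest of the other splits was also 2. This share is under 0.05 and argues against chance for the count in the main setting only. The real count fell to 0 with DESeq2, with a minimum count of 10, with the 2 groups alone and without some libraries. Chance is therefore not excluded. For single circRNAs and for gene lists the real counts were 0, which any split reaches (100 of 100, with up to 3 circRNAs and 2 lists in the others), so the splits test nothing there.

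Of 212 groups of 5 libraries, 22 had a highest or lowest library far from the other 4. For normally distributed values the rule flags about 1 in 20 groups, or 10.6, but these counts are sparse and skewed. A group with reads in 1 library alone is always flagged, and some of the values share reads. The 22 are therefore given as a description and not as an excess over chance. Sham 1 had 30213 reads, against 18176 to 21509 in the other sham libraries. It also detected 5368 circRNAs, against 3797 to 4077. Sleeve gastrectomy 4 had 80.5% of its reads in exonic circRNAs, against 83.6% to 84.7%. Dennd1b in sham 3 was at 914 CPM, against 2359 to 2913. CircRNA5889 of Dennd1b was at 143.8 CPM in sleeve gastrectomy 3 and at 0 in the other sleeve gastrectomy libraries. CircRNA6961 of Ttc39c was at 320.2 CPM in sham 5 and at 0 in the other sham libraries. CircRNA1854 of Slc33a1 was at 146 CPM in sham 3 and at 0 in the other sham libraries. CircRNA122 of Ppp2r5a was at 936 CPM in sleeve gastrectomy 1, against 647 to 728. The intergenic circRNA6045 had 35752 RPM in sham 4, against 11220.3 to 15621, and 0 in sleeve gastrectomy 3, against 11697 to 15406.

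Among the hosts, values in CPM, Pik3c2a was at 2696 in sleeve gastrectomy 2 (others 408 to 896). In sleeve gastrectomy 1, Canx was at 2964 (others 1837 to 2048) and Hmgcs1 at 465 (others 45.3 to 137). In sleeve gastrectomy 3, Rps6kb1 was at 614 (others 0 to 174), Hsp90b1 at 683 (others 0 to 89.6) and Aldh4a1 at 1638 (others 635 to 851). Pbld1 was at 896 in sleeve gastrectomy 5 (others 291 to 409.5). In sham 1, Fasn was at 91.0 (others 0) and Epb41 at 910.3 (others 261 to 358). In sham 2, Hsp90b1 was at 357 (others 0), and in sham 4, Ltbp1 was at 64.0 (others 179 to 214) and Rere at 4093 (others 5780.2 to 6319.8).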

How the results depend on the processing

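All alternatives here were planned before the data were examined except 3 added after they were seen: the entries of a junction summed, host names as written in the table, and symbol entries only. Changes of a pseudocount and of a filter on normalised values were planned only for a table of normalised values and were not run, and the prior count of 2 in the log2 CPM of the gene list tests was not changed. The filter on low counts was changed, as given below. Of 1335 values of named circRNAs and hosts under alternatives other than left-out libraries, 1287 kept their direction and their side of the threshold, 21 lost the call, 8 gained one and 19 reversed. With each library left out, 1093 of 1162 kept both, 23 lost the call, 5 gained one and 41 reversed. Most of these values belong to circRNAs and hosts that were not past the threshold and had no call to lose. Called hosts were less stable: with a library left out, Dennd1b kept its call in 4 of 10 fits and Upp2 in 2 of 10. Under the other alternatives Dennd1b kept it in 5 of 10, Upp2 in 6 of 10 and Nfatc2 in 4 of 10 in each comparison. Of the other results 73 of 103 values were kept under other alternatives and 177 of 228 with a library left out. With 1 relapse library left, that library is assumed to vary like the other groups. Depth limits single circRNAs, since at 18176 reads a count of 0 allows up to 165 RPM. Except where named, the cause was not tested.

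The number of circRNAs past the threshold was 0 in each comparison and changed as follows, in the order sleeve gastrectomy against sham, relapse against sleeve gastrectomy and relapse against sham. The DESeq2 Wald test gave 0, 2 (circRNA2052 and circRNA9738) and 1 (circRNA9738), limma-voom gave 0, 2 (circRNA2133 and circRNA2829) and 0, and no filter gave 0, 3 (ciRNA177, circRNA2829 and circRNA6102) and 1 (ciRNA177). With each library left out the count was 0 for the first comparison, 0 to 6 for the next (6 without relapse 2) and 0 to 5 for the last (5 without relapse 2). CircRNA2829 and circRNA9738 are each 1 of the 2 entries of a junction. With the entries of a junction summed, edgeR gave 0, 0 and 0, as it did without summing, and the other tools and filters were not run on summed entries.

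The number of host genes past the threshold was 2, 1 and 2. It was 0, 0 and 2 with the DESeq2 Wald test, 2, 2 and 3 with no filter (ENSRNOG00000049727 beside Nfatc2 in the middle comparison), 0, 0 and 1 with a minimum count of 10, 0, 0 and 1 with the 2 groups alone, 0, 0 and 1 with host names as written, and 1, 0 and 1 with symbol entries only, where Acly and Upp2 were the hosts called. With DESeq2 size factors it was 2, 1 and 3, and with library totals alone 2, 1 and 3. With each library left out it was 0 to 2 for sleeve gastrectomy against sham, 0 to 1 for relapse against sleeve gastrectomy and 0 to 5 for relapse against sham (0 without relapse 1, 5 without sham 5). Acly kept its call under all 10 alternatives other than left-out libraries, and Upp2 under 6, Dennd1b under 5 and Nfatc2 under 4 and 4 of 10.

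The labels do not state whether equal replicate numbers mark paired samples, and no pairing was detected. The residuals also carry counting error, so a weak pairing could go unseen. Across circRNAs, residuals of libraries with the same number correlated at −0.0654 to 0.0137 between sleeve gastrectomy and sham, within the −0.0807 to 0.0888 of libraries with different numbers, and 0 of the 5 sleeve gastrectomy libraries had its best match in the sham library of its own number. A block of the number gave 1, 2 and 1 circRNAs (circRNA2691 in each comparison, with circRNA2889 in the middle one), 2, 1 and 3 host genes and 0, 1 and 0 gene lists (secreted proteins and complement, adjusted p = 0.0362 in place of 0.235). It reversed Ikzf1 (0.48, 0.22 and 0.70 on the log2 scale in the 3 comparisons), Tgfbr2 (0.43) and Jag1 (0.21) in relapse against sleeve gastrectomy, and Rbfox2 in relapse against sham (−0.0092). The gene lists stayed at 0 with an estimated correlation, fry and library totals, and with each library left out (0 to 0).

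Summed entries reversed the log2 fold change of circRNA2829 in sleeve gastrectomy against sham to 0.57 and of circRNA6961 in relapse against sleeve gastrectomy to 0.38, since each sum adds the reads of the other entry. Reversals with limma-voom were Adgre1 (−0.49) and Ikzf1 (1.15) in sleeve gastrectomy against sham, Hnrnpm (0.031) in relapse against sleeve gastrectomy and Ikzf1 (0.87) in relapse against sham. Hnrnpm in relapse against sleeve gastrectomy, −0.01, also reversed with no filter (0.025), the 2 groups alone (0.029) and host names as written (0.012). In relapse against sham, host names as written reversed Xpo7 (−0.21) and Rbfox2 (−0.23), and symbol entries only gave −0.21 and −0.22.

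With a library left out, the log2 fold changes that reversed were, in sleeve gastrectomy against sham, Pik3c2a (−0.038 to 1.09), Adgre1 (−0.44 to 0.84), Ikzf1 (−0.52 to 0.62), Flt1 (−0.026 to 0.55), Vwf (−0.22 to 0.99), Xpo7 (−0.26 to 0.21) and Rbfox2 (−1.28 to 0.11). In relapse against sleeve gastrectomy they were Gbe1 (−0.033 to 1.16), Suclg1 (−0.15 to 2.25), Ltbp1 (−0.43 to 0.89), Tgfbr2 (−1.14 to 0.61), Adgre1 (−5.54 to 0.079), Prex2 (−2.32 to 0.42), Flt1 (−0.18 to 0.39), Jag1 (−5.05 to 0.57), Epb41 (−5.22 to 0.077), Rbfox2 (−0.048 to 1.55) and Hnrnpm (−0.71 to 0.44). In relapse against sham they were Suclg2 (−0.98 to 0.020), Sucla2 (−4.46 to 1.39), Tgfbr2 (−1.67 to 0.10), Ikzf1 (−1.20 to 0.15), Adgre1 (−5.07 to 0.49), Prex2 (−2.43 to 0.32), Jag1 (−3.36 to 2.26), Xpo7 (−0.11 to 0.39), Irak3 (−0.16 to 1.84) and Rbfox2 (−0.36 to 0.67). None of these passed the threshold with all libraries.

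The correlation of the 2 contrasts ranged from −0.382 to −0.168 with a library left out and from −0.308 to −0.265 under the other alternatives. The difference in detected circRNAs for relapse minus sleeve gastrectomy, −77 with at least 1 read, was 167.6 with at least 2 and 224.7 with at least 5 reads, and for relapse minus sham, 108.6, it was −195 after thinning to 18176 reads. As a share of distinct circRNAs instead of reads, relapse minus sleeve gastrectomy was −0.319 percentage points for intronic and 0.218 for intergenic circRNAs, and relapse minus sham was 0.0731 for intergenic circRNAs.

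With a library left out, the difference in detected circRNAs ranged from −28.7 to 477 for sleeve gastrectomy minus sham, from −1128 to 974 for relapse minus sleeve gastrectomy and from −942 to 1159.6 for relapse minus sham. The difference in reads ranged from −5483 to 13273 for relapse minus sleeve gastrectomy and from −3338 to 15418 for relapse minus sham. In percentage points, sleeve gastrectomy minus sham ranged from −0.879 to 0.183 for exonic, 0.608 to 0.992 for intronic and −0.968 to 0.266 for intergenic circRNAs. Relapse minus sleeve gastrectomy ranged from −0.218 to 1.20, −0.675 to 0.833 and −1.09 to 0.146 for the same types, and relapse minus sham from −0.728 to 0.657 for exonic circRNAs. The pseudo-F of sleeve gastrectomy against sham ranged from 1.11 to 1.19, with an exact permutation p of 0.0476 without sleeve gastrectomy 5, that of relapse against sleeve gastrectomy from 0.774 to 1.28 and that of relapse against sham from 0.815 to 1.5001, both lowest without relapse 1.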

Other observations

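The choice of the tables described here and the test of 200 KEGG pathways were made after the data had been seen. The gene lists were fixed beforehand, but the sums over them were not among the planned tests. Tf, which encodes the iron carrier transferrin of plasma, gave 70 distinct junctions from 882 reads in the 12 libraries, 3164 ± 738 RPM (SD, n = 12). LOC297568 gave 69, Dpyd, the first enzyme of pyrimidine breakdown, 49, Cps1 of the urea cycle 34, complement C3 33, Pik3c2g 33 and Pck1 of gluconeogenesis 31. The 69 of LOC297568 summed to 1058 ± 769 RPM and the 31 of Pck1 to 876 ± 246 RPM, while Sult1c3 had 6385 ± 2807 RPM with 1 junction and Psd3 5466 ± 1146 RPM with 20.

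Summed over its circRNAs, Spidr had 2.22% of all back-splice reads, Cyp2c7 1.86%, Nf1x 1.83%, Cdyl 1.12%, Ugt2b35 1.002% and Lrp6, a coreceptor of Wnt signalling, 0.900%. The 10 hosts with most reads had 11.4% and the 100 hosts with most reads 34.0% of the reads, and 2314 of the 6026 hosts gave a single junction. Genes of xenobiotic metabolism summed to 40815 ± 7389.7 RPM in sham, 39162.5 ± 3909 after sleeve gastrectomy and 33449 ± 4433 in relapse (SD, n = 5, 5 and 2). Secreted proteins and complement summed to 24666 ± 3749, 24945 ± 2672 and 20146 ± 1596 RPM, and genes of amino acids and urea cycle to 19100.2 ± 5102, 17429 ± 4886 and 16705 ± 567 RPM. The widely conserved circRNA hosts summed to 54667 ± 4632, 57774 ± 6425 and 56851 ± 322 RPM. Among these sums the smallest exact permutation p was 0.0952, for secreted proteins and complement in relapse against sleeve gastrectomy. With 2 against 5 libraries the smallest p such a test can give is 0.0476, too large to pass when adjusted over 63 sums, so the sums are given as values.

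The intergenic circRNA2691, on chromosome 5 at 77368025 to 77564788, had reads in 1 sleeve gastrectomy and 1 relapse library. Its group levels were 0 CPM in sham, 9679 ± 21643 after sleeve gastrectomy and 6383 ± 9027 in relapse. It did not pass in edgeR in any comparison (adjusted p = 0.997, 1 and 0.909). It passed in all 3 with the replicate number as a block, although no pairing by that number was detected.

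Between libraries, the Spearman correlation of circRNA levels was 0.403 to 0.581, with a median of 0.503. Of 200 KEGG pathways tested with camera, 0 passed in each comparison, with 10, 6 and 6 at an unadjusted p under 0.05 for sleeve gastrectomy against sham, relapse against sleeve gastrectomy and relapse against sham, where 10 would arise by chance. The smallest adjusted p were 0.407 for Alzheimer disease (11 hosts, lower, p = 0.0163 with an estimated correlation), 0.928 for ferroptosis (5 hosts, lower, p = 0.05001) and 0.766 for natural killer cell mediated cytotoxicity (6 hosts, lower, p = 0.0554).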
